A study of Homo sapiens with 18 samples.

How the data were processed

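Total RNA of 3 established head and neck squamous cell carcinoma lines, SQ20B, FADU and Cal 27, was compared after 48 h in 5 uM erlotinib or in 0.01% DMSO, with 3 replicates in each of 6 groups and 18 arrays in all. Per the labels, cells grew in DMEM with 10% fetal bovine serum, RNA was extracted with QIAGEN RNeasy columns and DNase treatment and checked on an Agilent Bioanalyzer, and biotinylated cRNA was made with the Ambion TotalPrep kit. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. How arrays were assigned to slides is not given in the sources used here.

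The submitters' processing notes name GenomeStudio 2011.1 for the arrays. Per the file headers, the deposited table holds for each array an average signal intensity, a detection p-value and the number of beads per probe. The deposited intensities had been background-subtracted, as negative values show. They had also been quantile-normalized in 2 sets, 12 SQ20B and FADU arrays and 6 Cal 27 arrays, since sorted log2 values differed by at most 0.086 and 0.039 within the sets. The detection p-values were made by the authors' software before deposit from negative control beads, a step inferred from the column name. The deposited log2 values of the second table equalled the log2 of intensity plus 31, to within 5.6e-05, an offset found from the values. The median number of beads per probe was 22.

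Before the data were examined, the tests, alternatives, named-gene rule and 26 gene lists were fixed, on the assumption of raw intensities that limma's neqc would correct and normalize with an offset of 16. The files showed values already corrected and normalized, so the deposited log2 values were used instead and neqc became an alternative. The offset of 31 makes fold changes of dim genes smaller than they would be without it. Cal 27 arrays were normalized apart from the others, but each contrast of erlotinib and vehicle lies within a set.

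Of 47231 probes, 30113 carried 1 gene symbol, 8 carried several and 17110 none, and 30074 were found in a RefSeq table that changed 0 symbols. Probes detected at p below 0.05 on at least 3 arrays were kept, 25610 in all and 18585 of them named. Each of 13571 genes was represented by its kept probe with the highest mean over all arrays, and 3800 genes had more than 1 kept probe. Among all genes chosen by the rule for named genes given below, of which the text uses a part, 160 calls in a line could be compared with another probe. Another probe was called in the same direction for 114 of these, no other probe was for 46, and 1 was called in the opposite direction.

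A limma model of 6 group means (limma 3.58.1, R 4.3.3) was fitted with empirical Bayes moderation and 12 residual degrees of freedom. Erlotinib was compared with vehicle within each line, and the 3 pairwise differences of these effects were tested. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Genes called in the same direction in all 3 lines were counted and compared with the number expected from independent lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

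Gene lists with at least 5 tested members were tested within each line by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were alternatives. The lists were ERK pathway target genes, EGFR family with ligands and regulators, inflammatory cytokines and chemokines, NF-kB target and feedback genes, Toll-like and IL-1 receptor signalling, interferon-stimulated genes, MHC antigen presentation, NADPH oxidase components, NRF2 and antioxidant genes, DNA replication and G1/S genes, mitosis and G2/M genes, ribosome biogenesis, cholesterol synthesis and uptake, glycolysis and hypoxia, keratinocyte differentiation, basal keratinocyte genes, mesenchymal transition, amino-acid and ER stress, p53 targets, lysosome and autophagy, FOXO and growth arrest, apoptosis regulators, leukocyte, fibroblast and endothelial markers, and reference genes. List members were chosen from general knowledge and are not independent of one another. Tests of list differences between lines were added after the data had been examined.

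Named genes followed a rule set in advance. They were the 6 largest rises and falls per line among called genes whose 3 erlotinib arrays all lay on 1 side of the vehicle arrays, up to 2 risen and 2 fallen members per list, 10 rises and 10 falls shared by all lines, and the 6 largest differences in each direction between lines. EGFR, DUSP6, CCND1, MYC, IL6, CXCL8, IL1A, IL1B, NOX4 and MYD88 were named whatever their result. The text uses a part of this selection. All genes of the last group appear in the text.

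The procedure was tested on simulated data in which known changes were added to 67, 67 and 66 genes at log2 sizes of 0.5, 1 and 2. The share recovered was 32.8%, 80.6% and 98.5% in SQ20B, 11.9%, 80.6% and 98.5% in FADU, and 28.4%, 86.6% and 100% in Cal 27. All lines were simulated with the same spread per gene, so differences between lines in these shares reflect random draws. Far fewer genes were changed than were called in the data, so the shares need not hold for the real comparisons. False calls made up 7%, 7.3% and 5% of the calls in the same lines. A shifted list was called in each line and 0 other lists were. Genes were simulated as independent, so this does not test false calls of lists whose members are correlated.

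Alternatives were neqc, quantile normalization of log2 intensities with no offset and values under 1 set to 1, no detection filter, a stricter filter (p below 0.01 on all 3 arrays of a group), a replicate block, an intensity trend with robust variance, each line alone, every probe on its own, probes averaged per gene, and leaving out each array in turn. A fit without 2 Cal 27 arrays was added after the data had been examined.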

Results

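Gene expression was measured on 18 Illumina bead arrays from 3 head and neck squamous cell carcinoma lines, SQ20B from the larynx, FADU from the pharynx and Cal 27 from the tongue. Cells of each line were kept for 48 h in 0.01% DMSO, the vehicle, or in 5 uM erlotinib, an inhibitor of the EGFR tyrosine kinase, with 3 arrays in each of the 6 groups. Of 47231 probes, between 18288 and 21904 were detected per array at a detection p below 0.05. Vehicle arrays detected 20236 to 21904 probes in SQ20B, 19532 to 20624 in FADU and 18527 to 19256 in Cal 27. Erlotinib arrays detected 20415 to 20854, 19356 to 19776 and 18288 to 20390 probes in the same order. Log2 values of arrays within a group correlated at 0.969 to 0.987 across probes, and 13571 genes were tested, each through 1 probe. The number of arrays limits the precision of every value below. Genes described as risen or fallen passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, errors are standard errors (SE) of log2 changes unless named SD, and n = 3 per group throughout.

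The first comparison asked which genes changed with erlotinib in SQ20B. CYP1A1, a cytochrome P450 enzyme, rose 43.1-fold (log2 change 5.43, SE 0.26), the largest rise in this line (limma, Benjamini-Hochberg adjusted p = 3.04e-10). FOLR1, a folate receptor, rose by a log2 change of 3.38 (SE 0.23), the actin-binding gene TAGLN by 3.20 (SE 0.22), CLIC3 by 2.57 (SE 0.19), the keratin KRT16 by 2.47 (SE 0.22) and the cyclin-dependent kinase inhibitor CDKN2B by 2.31 (SE 0.17). EGR1, an immediate early transcription factor, fell 17.3-fold (log2 change -4.11, SE 0.25), and MALL and the cytokine gene IL24 had log2 changes of -2.86 (SE 0.16) and -2.66 (SE 0.14). DUSP6, a phosphatase that acts on ERK, fell 9.04-fold (log2 change -3.18, SE 0.20) and was detected on 2 of the 3 erlotinib arrays. Its second probe fell as well, by a log2 change of -1.72. ETV5, a transcription factor, was undetected on all erlotinib arrays and fell at least 4.75-fold by its named probe, while its other probe was not called (-0.43). For such genes the bound compares the mean of the brighter group with a dim-group mean in which each array contributes its lowest detected signal or the probe's own signal, whichever was higher. The calcium-binding protein gene CALB2 fell at least 21.3-fold by 1 probe, but its other probe was not called, with a log2 change of 0.28.

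Genes downstream of ERK fell together in SQ20B. Of 19 tested ERK pathway target genes, 17 fell, 1 rose and 1 was not called (18 fallen and 1 risen adjusted over the list alone; camera in limma, Benjamini-Hochberg adjusted p = 3.56e-14). FOSL1, a component of the AP-1 transcription factor, had a log2 change of -2.54, the cyclin gene CCND1 -0.96 (SE 0.16) and MYC -0.90 (SE 0.13). Cell cycle lists moved the furthest: 28 of 30 DNA replication and G1/S genes and all 30 mitosis and G2/M genes fell, with the same counts adjusted over the list alone (camera adjusted p = 1.76e-33 and 3.41e-34). CDC45, needed for replication origin firing, changed by -2.30 (SE 0.12), UHRF1 by -2.28 (SE 0.13), HMMR by -2.09 (SE 0.15) and the mitotic kinesin KIF2C by -1.84 (SE 0.14). Ribosome biogenesis genes fell in 17 of 27 cases and 10 were not called (20 fallen adjusted over the list alone, camera adjusted p = 1.98e-09). BOP1 and NOLC1 were examples, at -1.43 (SE 0.14) and -1.14 (SE 0.14). Of 24 glycolysis and hypoxia genes 11 fell, 1 rose and 12 were not called (12 fallen and 1 risen adjusted over the list alone, camera adjusted p = 1.15e-05). The glycolytic enzymes LDHA and ENO1 fell 2.45-fold and 1.97-fold (log2 changes -1.29, SE 0.15, and -0.98, SE 0.11). Reference genes also moved, with 5 of 11 fallen, 0 risen and 6 not called (7 fallen and 1 risen adjusted over the list alone, camera adjusted p = 0.00482), among them HPRT1 (-0.93, SE 0.15).

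Stress, lysosomal and interferon genes rose in SQ20B. Amino-acid and ER stress genes rose in 13 of 21 cases, 1 fell and 7 were not called, as they did adjusted over the list alone (camera adjusted p = 1.31e-05), with the transcription factors DDIT3 (1.42, SE 0.16) and ATF4 (1.37, SE 0.14) among the risen. Lysosome and autophagy genes rose in 13 of 20 cases and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.35e-06). WIPI1 and MAP1LC3B, which act in autophagosome formation, rose by 1.41 (SE 0.14) and 1.20 (SE 0.21), while the lysosomal enzyme gene GLA had a log2 change of -1.07 (SE 0.14). FOXO and growth-arrest genes rose in 9 of 17 cases and none fell, also adjusted over the list alone (camera adjusted p = 6.11e-06). KLHL24 at 1.92 (SE 0.17) and YPEL5 at 1.66 (SE 0.14) led this group. Interferon-stimulated genes rose in 14 of 27 cases, 1 fell and 12 were not called (17 and 1 adjusted over the list alone, camera adjusted p = 1.17e-06). That list was not called at adjusted p = 0.156 with an estimated correlation. IRF9 rose 3.51-fold (log2 change 1.81, SE 0.20) and the antiviral gene MX1 rose 3.02-fold (1.60, SE 0.22), with an SD of 0.68 among the MX1 erlotinib arrays. Among 20 MHC antigen presentation genes 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00573, but adjusted p = 0.107 with an estimated correlation). HLA-B (1.36, SE 0.17) and HLA-F (1.13, SE 0.12) rose.

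Cytokine genes of SQ20B moved in both directions, with 4 of 22 inflammatory cytokines and chemokines risen, 4 fallen and 14 not called, the same adjusted over the list alone (camera adjusted p = 0.38). IL32 rose 4.56-fold (log2 change 2.19, SE 0.18) and IL6 2.84-fold (1.51, SE 0.15), while the neutrophil chemokine gene CXCL8 had a log2 change of -1.13 (SE 0.15). IL1B fell by 0.50 (SE 0.17, limma with Benjamini-Hochberg, adjusted p = 0.0384), a call lost without vehicle array 1 or 2 or erlotinib array 2 or 3, at adjusted p values of 0.0682, 0.161, 0.114 and 0.185, with no offset (adjusted p = 0.0576) and with no detection filter (adjusted p = 0.0697). IL1A was not called (-0.28, SE 0.20). MYD88, the adaptor of Toll-like and IL-1 receptors, rose by 0.74 (SE 0.16, adjusted p = 0.00162). NOX4 was not tested because its 2 probes were detected on 0 and 1 of 18 arrays. EGFR itself was not called (0.04, SE 0.16), whereas the EGFR ligand gene HBEGF and the feedback inhibitor gene ERRFI1 changed by -0.98 (SE 0.15) and -1.06 (SE 0.15). Matrix metalloproteinase genes MMP10 and MMP1 fell 2.66-fold and 2.46-fold, and the death receptor ligand gene TNFSF10 rose 2.76-fold (1.47, SE 0.20). Across the transcriptome 3394 genes, 25% of those tested, were called in SQ20B, 1700 risen and 1694 fallen, of which 292 and 426 changed at least 2-fold.

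The second comparison asked the same of FADU. CYP1A1 rose at least 67.6-fold (limma with Benjamini-Hochberg, adjusted p = 2.51e-11), a bound because 1 of 3 vehicle arrays detected it. ATP6V1B1, a subunit of the vacuolar proton pump, rose 14.1-fold (3.81, SE 0.15), the stress gene NUPR1 14-fold (3.81, SE 0.19), CLIC3 13.1-fold (3.71, SE 0.19) and LCN2, which binds siderophores, 9.92-fold (3.31, SE 0.14). FOLR1 rose 12.5-fold (3.64, SE 0.23), with detection on 2 of 3 vehicle arrays. FOSL1 fell 12.6-fold (-3.65, SE 0.18), the neuropeptide gene GAL fell 9.92-fold (-3.31, SE 0.16), EGR1 fell 7.43-fold (-2.89, SE 0.25) and the lipoprotein receptor gene LRP8 fell 7.13-fold (-2.83, SE 0.15). ETV5 went from detected on every vehicle array to undetected on every erlotinib array, a fall of at least 3.4-fold by its named probe, with the other probe at -0.50 and not called. The 2 probes of CALB2 were called in opposite directions, at log2 changes of -2.71 (SE 0.19) and 0.79. DUSP6 fell 3.03-fold (-1.60, SE 0.20), and its other probe fell by 0.61.

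Growth genes fell in FADU as well. Of 19 ERK pathway target genes 14 fell and 5 were not called (15 fallen adjusted over the list alone, camera adjusted p = 8.23e-10), including CCND1 (-1.09, SE 0.16). MYC fell by 0.41 (SE 0.13, limma with Benjamini-Hochberg, adjusted p = 0.0206), but was not called without vehicle array 3 or erlotinib array 3 (-0.31 and -0.37, at adjusted p values of 0.112 and 0.0666). Its other probe was called at -0.48. DNA replication and G1/S genes fell in 27 of 30 cases (28 adjusted over the list alone, camera adjusted p = 1.4e-22), and mitosis and G2/M genes in 22 of 30 (24 adjusted over the list alone, camera adjusted p = 1.62e-08). CDC45 changed by -2.07 (SE 0.12), the cyclin gene CCNA2 by -1.42 (SE 0.12) and CDC20 by -1.03 (SE 0.12). Ribosome biogenesis genes fell in 24 of 27 cases (25 adjusted over the list alone, camera adjusted p = 2.28e-15), with RRS1 at -1.72 (SE 0.14) and NOLC1 at -1.70 (SE 0.14). Of 24 glycolysis and hypoxia genes 16 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 5.64e-05). LDHA fell 3.53-fold (-1.82, SE 0.15) and the peptide hormone gene ADM rose 1.98-fold (0.99, SE 0.14). The p53-induced exonuclease gene AEN fell 4.6-fold (-2.20, SE 0.16).

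The risen groups in FADU included 11 of 21 amino-acid and ER stress genes with 2 fallen, also adjusted over the list alone (camera adjusted p = 0.000264). DDIT4, an inhibitor of mTORC1, and DDIT3 rose 2.87-fold (1.52, SE 0.19) and 2.86-fold (1.51, SE 0.16). Lysosome and autophagy genes rose in 12 of 20 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 5.04e-05), with GABARAPL1 at 1.68 (SE 0.13) and WIPI1 at 1.60 (SE 0.14). FOXO and growth-arrest genes rose in 11 of 17 cases and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 1.54e-05, but adjusted p = 0.0604 with an estimated correlation). YPEL3 rose 6.12-fold (2.61, SE 0.15), TXNIP 5.94-fold (2.57, SE 0.18), and the insulin receptor substrate gene IRS1 fell 3.42-fold (-1.77, SE 0.13). MHC antigen presentation genes rose in 10 of 20 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0013, but adjusted p = 0.0616 with an estimated correlation), with HLA-DMA at 1.35 (SE 0.14). Keratin genes changed in both directions. KRT15 rose 6.09-fold (2.61, SE 0.15), KRT13 4.16-fold (2.06, SE 0.19) and KRT4 4.12-fold (2.04, SE 0.17), while KRT14 fell 5.22-fold (-2.38, SE 0.19). TGFBI, an extracellular matrix gene, rose 3.4-fold (1.77, SE 0.15).

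Interferon-stimulated genes had no common direction in FADU, with 5 of 27 risen and 11 fallen (6 and 11 adjusted over the list alone, camera adjusted p = 0.499). IRF9 rose by 1.23 (SE 0.20) and ISG20, an exonuclease gene, changed by -1.27 (SE 0.16). Among 22 inflammatory cytokines and chemokines 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.45, with a median of 0.11, a mean of -0.17 and a downward test). CXCL8 fell 3.24-fold (-1.70, SE 0.15), the chemokine gene CCL5 2.87-fold (-1.52, SE 0.20), IL1B 2.18-fold (-1.12, SE 0.17) and IL1A 1.76-fold (-0.81, SE 0.20), while CXCL16 rose 1.69-fold (0.75, SE 0.11). IL6 was not called (0.37, SE 0.15, limma with Benjamini-Hochberg, adjusted p = 0.0645), and MYD88 was not called (0.09, SE 0.16). NOXA1, an activator of NADPH oxidase 1, rose 3.28-fold (1.71, SE 0.20). EGFR rose 1.97-fold (0.98, SE 0.16), as did 1 of its 3 other probes (0.87), with -0.26 and 0.09 at the remaining 2. The ligand gene EREG fell at least 1.73-fold and ERRFI1 fell 2.38-fold (-1.25, SE 0.15). In FADU 4640 genes were called, 34.2% of those tested, with 2322 risen and 2318 fallen, and 545 and 461 of these changed at least 2-fold.

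The third comparison concerned Cal 27. CYP1A1 rose at least 50.8-fold (limma with Benjamini-Hochberg, adjusted p = 9.03e-11), with detection on 1 of 3 vehicle arrays. The histone gene H2AC18 rose 8.39-fold (3.07, SE 0.19), NUPR1 8.32-fold (3.06, SE 0.19) and LOXL4, a lysyl oxidase family gene, 8.08-fold (3.01, SE 0.20). MUC4, a membrane mucin gene, rose 10.2-fold (3.35, SE 0.24) by its named probe, and its 2 other probes were not called. ABCA13, a transporter gene, rose at least 3.24-fold from vehicle arrays that did not detect it. KRT13 fell 7.81-fold (-2.97, SE 0.19), the noncoding RNA gene SNAR-A1 fell 7.21-fold (-2.85, SE 0.29), NRG1, a ligand of the ERBB3 and ERBB4 receptors, fell 5.88-fold (-2.56, SE 0.13) and MCM6, a replicative helicase subunit, fell 5.06-fold (-2.34, SE 0.12). Other NRG1 probes were at -0.83 (called) and -0.07 (not called). The histone gene H4C3 fell 9.03-fold (-3.18, SE 0.49), with an SD of 0.55 among its vehicle and 1.63 among its erlotinib arrays. Its SE pools all groups and was the same in SQ20B, where the SDs were 0.28 and 0.20.

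The cell cycle and ribosome lists fell in Cal 27. DNA replication and G1/S genes fell in 28 of 30 cases and mitosis and G2/M genes in all 30, with the same counts adjusted over the list alone (camera adjusted p = 7.92e-29 and 4.97e-26). UHRF1 changed by -2.24 (SE 0.13), the spindle checkpoint kinase gene BUB1 by -1.84 (SE 0.14) and CCNA2 by -1.82 (SE 0.12). Of 27 ribosome biogenesis genes 22 fell, also adjusted over the list alone (camera adjusted p = 9.26e-11), with NOP56 at -1.66 (SE 0.23). ERK pathway target genes fell in 9 of 19 cases, 3 rose and 7 were not called, also adjusted over the list alone (camera adjusted p = 0.0115). EGR1 (-2.27, SE 0.25), FOSL1 (-1.98, SE 0.18) and CCND1 (-1.02, SE 0.16) were among the fallen. DUSP6 fell 3.21-fold by its named probe (-1.68, SE 0.20), with -0.24 and no call at the other. MYC was not called by its named probe (0.08, SE 0.13), whereas its other probe fell by 0.43 (limma, Benjamini-Hochberg over all named probes, adjusted p = 0.0346). Glycolysis and hypoxia genes fell in 13 of 24 cases and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 0.00589, but adjusted p = 0.0847 with an estimated correlation). GAPDH changed by -0.76 (SE 0.14), while VEGFA rose 1.78-fold (0.83, SE 0.17). Keratinocyte differentiation genes fell in 9 of 24 cases and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00981, but adjusted p = 0.185 with an estimated correlation), with KRT13 the largest of them.

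MHC antigen presentation genes rose in Cal 27 in 14 of 20 cases and none fell, also adjusted over the list alone (camera adjusted p = 1.5e-09). The class II genes HLA-DPA1 and HLA-DRB1 rose 7.41-fold (2.89, SE 0.20) and 4.54-fold (2.18, SE 0.15). Inflammatory cytokines and chemokines rose in 8 of 22 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00576, but adjusted p = 0.0847 with an estimated correlation). IL32 rose 3.23-fold (1.69, SE 0.18), IL6 2.21-fold (1.14, SE 0.15) and CXCL8 1.79-fold (0.84, SE 0.15), while IL1A (0.40, SE 0.20), IL1B (0.14, SE 0.17) and MYD88 (-0.02, SE 0.16) were not called. NADPH oxidase components rose in 5 of 10 cases and none fell, also adjusted over the list alone (camera adjusted p = 0.0388, but adjusted p = 0.0847 with an estimated correlation), among them CYBA (1.12, SE 0.15) and DUOX2, by at least 1.69-fold. EGFR family, ligands and regulators rose in 5 of 11 cases and none fell, also adjusted over the list alone (camera adjusted p = 0.0213, but adjusted p = 0.153 with an estimated correlation). The ligand gene NRG1, which fell in Cal 27, was not among the tested members of this list. HBEGF rose 2.97-fold (1.57, SE 0.15) and ERBB3 2.3-fold (1.20, SE 0.16) by its named probe. Other ERBB3 probes were at 0.46 (called) and 0.12 (not called). EGFR rose 1.45-fold (0.54, SE 0.16, limma with Benjamini-Hochberg, adjusted p = 0.0131), a call lost without vehicle array 3 or erlotinib array 1 or 2 (0.46, 0.48 and 0.44, at adjusted p values of 0.0599, 0.0549 and 0.0609) or with the line alone (0.54, adjusted p = 0.0559). Of its 3 other probes 1 rose (0.87) and 2 were not called (0.62 and 0.29). The mitochondrial superoxide dismutase gene SOD2 rose 2.9-fold (1.53, SE 0.12) and the IL-1 receptor kinase gene IRAK2 2.7-fold (1.43, SE 0.16).

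Cholesterol synthesis and uptake genes of Cal 27 rose in 9 of 17 cases and none fell (10 adjusted over the list alone, camera adjusted p = 0.00335, but adjusted p = 0.0517 with an estimated correlation), with MSMO1 at 1.05 (SE 0.17) and SC5D at 0.98 (SE 0.15). Amino-acid and ER stress genes rose in 12 of 21 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00085), with DDIT3 at 1.83 (SE 0.16) and TRIB3 at 1.07 (SE 0.11). Of 20 lysosome and autophagy genes 13 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.22e-05), with WIPI1 at 1.24 (SE 0.14) and the sialidase gene NEU1 at 1.23 (SE 0.15). FOXO and growth-arrest genes rose in 10 of 17 cases and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 5.97e-06), led by PIK3IP1 (2.52, SE 0.16) and YPEL3 (2.17, SE 0.15). Apoptosis regulators rose in 8 of 20 cases and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0486, but adjusted p = 0.0847 with an estimated correlation). TNFSF10 rose 2.44-fold (1.29, SE 0.20) and CFLAR, an inhibitor of caspase 8 activation, 2.32-fold (1.21, SE 0.17). In Cal 27 4311 genes were called, 31.8% of those tested, with 2213 risen and 2098 fallen, of which 448 and 465 changed at least 2-fold.

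Several lists were not called in a line and are given here by their risen and fallen members, adjusted over the list alone only where that changed a count. NF-kB target and feedback genes had 4 risen and 2 fallen of 16 in SQ20B, 4 and 3 in FADU, and 8 and 2 in Cal 27 (camera in limma, Benjamini-Hochberg adjusted p = 0.416, 0.477 and 0.0509). Toll-like and IL-1 receptor signalling genes had 4 and 1, 3 and 2, and 7 and 1 of 18 (adjusted p = 0.18, 0.674 and 0.0606). NRF2 and antioxidant genes had 4 and 1, 2 and 7, and 3 and 7 of 17 (adjusted p = 0.426, 0.359 and 0.0855), with the aldo-keto reductase gene AKR1B10 at -1.27 (SE 0.18) in FADU and, with detection on 2 of 3 erlotinib arrays, -1.55 (SE 0.18) in Cal 27. Target genes of p53 had 6 and 3, 6 and 3, and 6 and 2 of 17 (adjusted p = 0.106, 0.359 and 0.0606). Basal keratinocyte genes had 1 and 2, 3 and 2, and 3 and 4 of 13 (adjusted p = 0.622, 0.777 and 0.367), and mesenchymal transition genes had 2 and 6, 2 and 6, and 1 and 2 of 18 (adjusted p = 0.0849, 0.384 and 0.443). Keratinocyte differentiation genes had 7 and 1 of 24 in SQ20B, and 8 and 3 in FADU (4 fallen adjusted over the list alone), at adjusted p values of 0.131 and 0.419. Cholesterol synthesis and uptake genes had 0 and 2 of 17 in SQ20B (1 fallen adjusted over the list alone), and 2 and 4 in FADU (adjusted p = 0.426 and 0.359). EGFR family genes had 1 and 4 of 11 in SQ20B and 4 and 4 in FADU (adjusted p = 0.209 and 0.899). NADPH oxidase components had 1 and 0 of 10 in SQ20B (0 adjusted over the list alone), and 4 and 0 in FADU (adjusted p = 0.416 and 0.14). Apoptosis regulators had 5 and 1 of 20 in SQ20B, and 4 and 2 in FADU (adjusted p = 0.0881 and 0.485), the FADU median being -0.02 with a mean of 0.14 and an upward test. Interferon-stimulated genes in Cal 27 had 4 and 5 of 27 (5 and 5 adjusted over the list alone, adjusted p = 0.897), with a median of 0.02, a mean of 0.03 and a downward test. Reference genes had 1 and 6 of 11 in FADU, and 1 and 3 in Cal 27 (adjusted p = 0.185 and 0.476), with ACTB at -0.58 (SE 0.11) and -0.71 (SE 0.11).

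Markers of other cell types were few on these arrays. Leukocyte markers had 0 risen and 1 fallen of 8 in every line (0 fallen in Cal 27 adjusted over the list alone), with camera in limma and Benjamini-Hochberg adjusted p values of 0.416, 0.899 and 0.314. Their FADU median was 0.08, with a mean of -0.01 and a downward test. Fibroblast markers had 1 risen and 0 fallen of 6 in every line (0 risen in FADU adjusted over the list alone), at adjusted p values of 0.914, 0.541 and 0.539. The Cal 27 median was -0.07, with a mean of 0.24 and an upward test, and the risen gene was the proteoglycan gene LUM (2.07, SE 0.15). Endothelial markers had 1 risen and 1 fallen of 5 in SQ20B, 2 and 1 in FADU, and 2 and 0 in Cal 27, also adjusted over the list alone (adjusted p = 0.947, 0.224 and 0.102). Their SQ20B median was -0.21, with a mean of 0 and an upward test. CDH5, the endothelial cadherin gene, rose 3.43-fold in FADU (1.78, SE 0.18) and 3.75-fold in Cal 27 (1.91, SE 0.18). In SQ20B it had a log2 change of -0.67 (SE 0.18, adjusted p = 0.00915), a call lost with no offset (adjusted p = 0.0745).

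**Figure D1:**
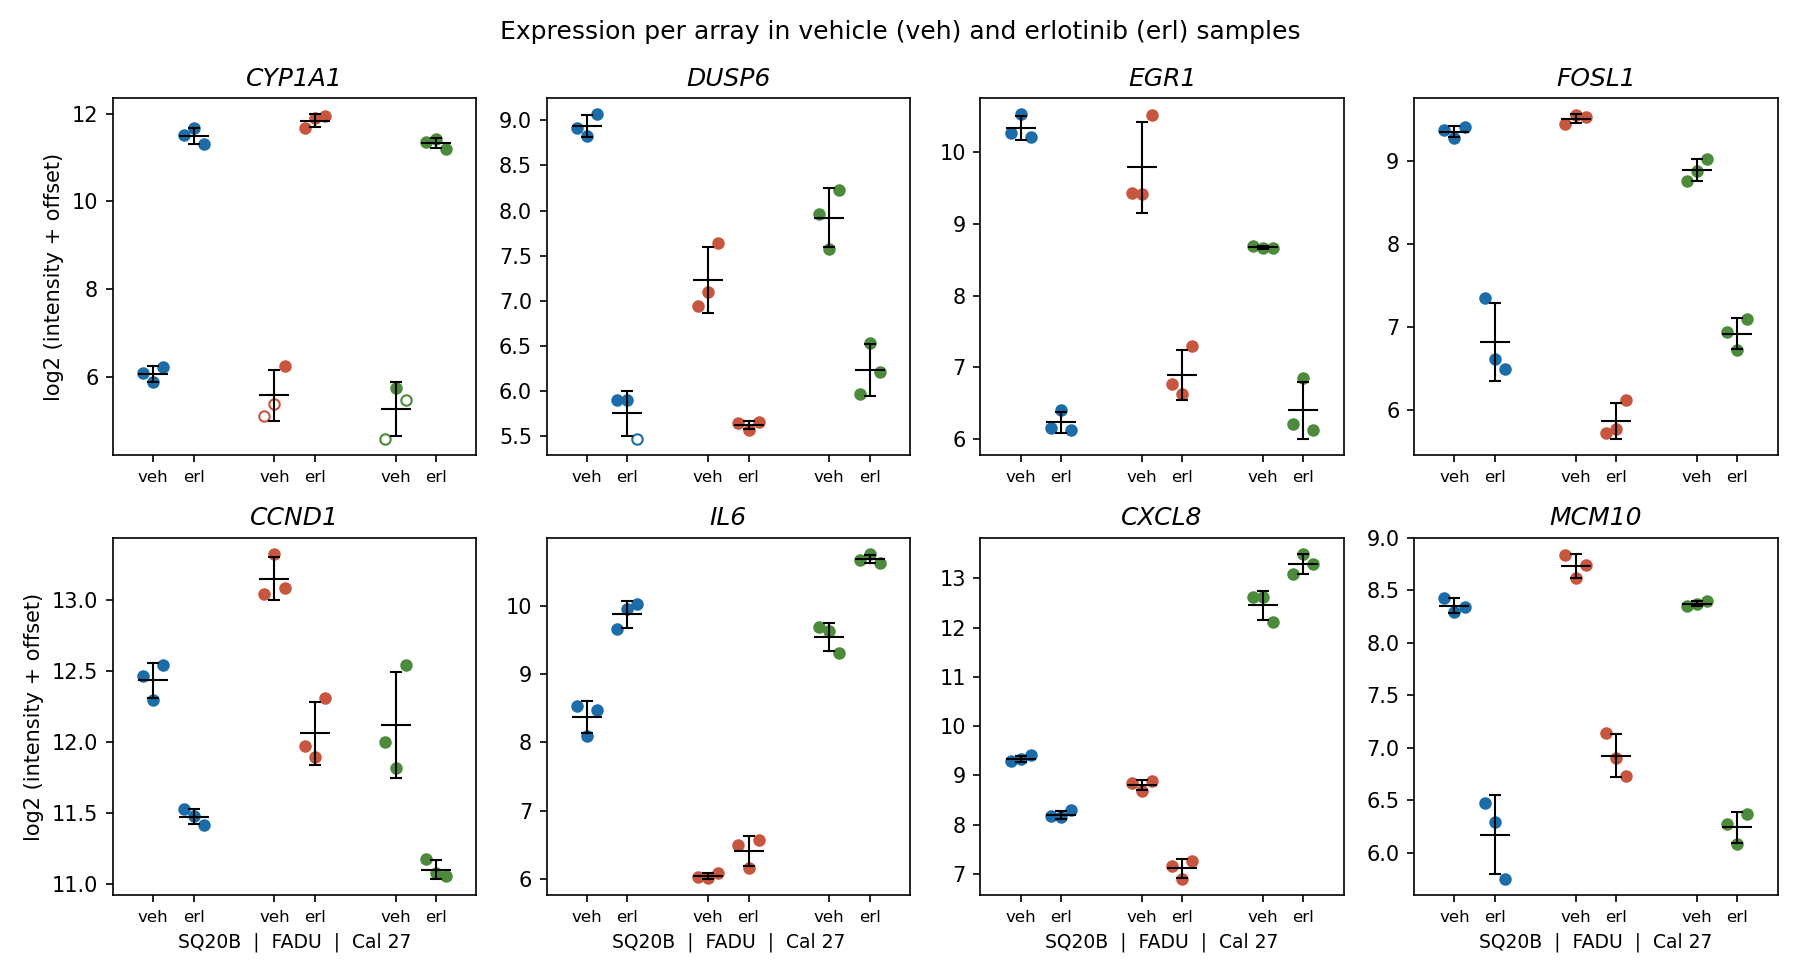
Log2 intensity of 8 genes on each of the 18 arrays by line and treatment. Filled points were detected, open points were not, and bars give the mean and SD of 3 arrays.

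**Figure D2:**
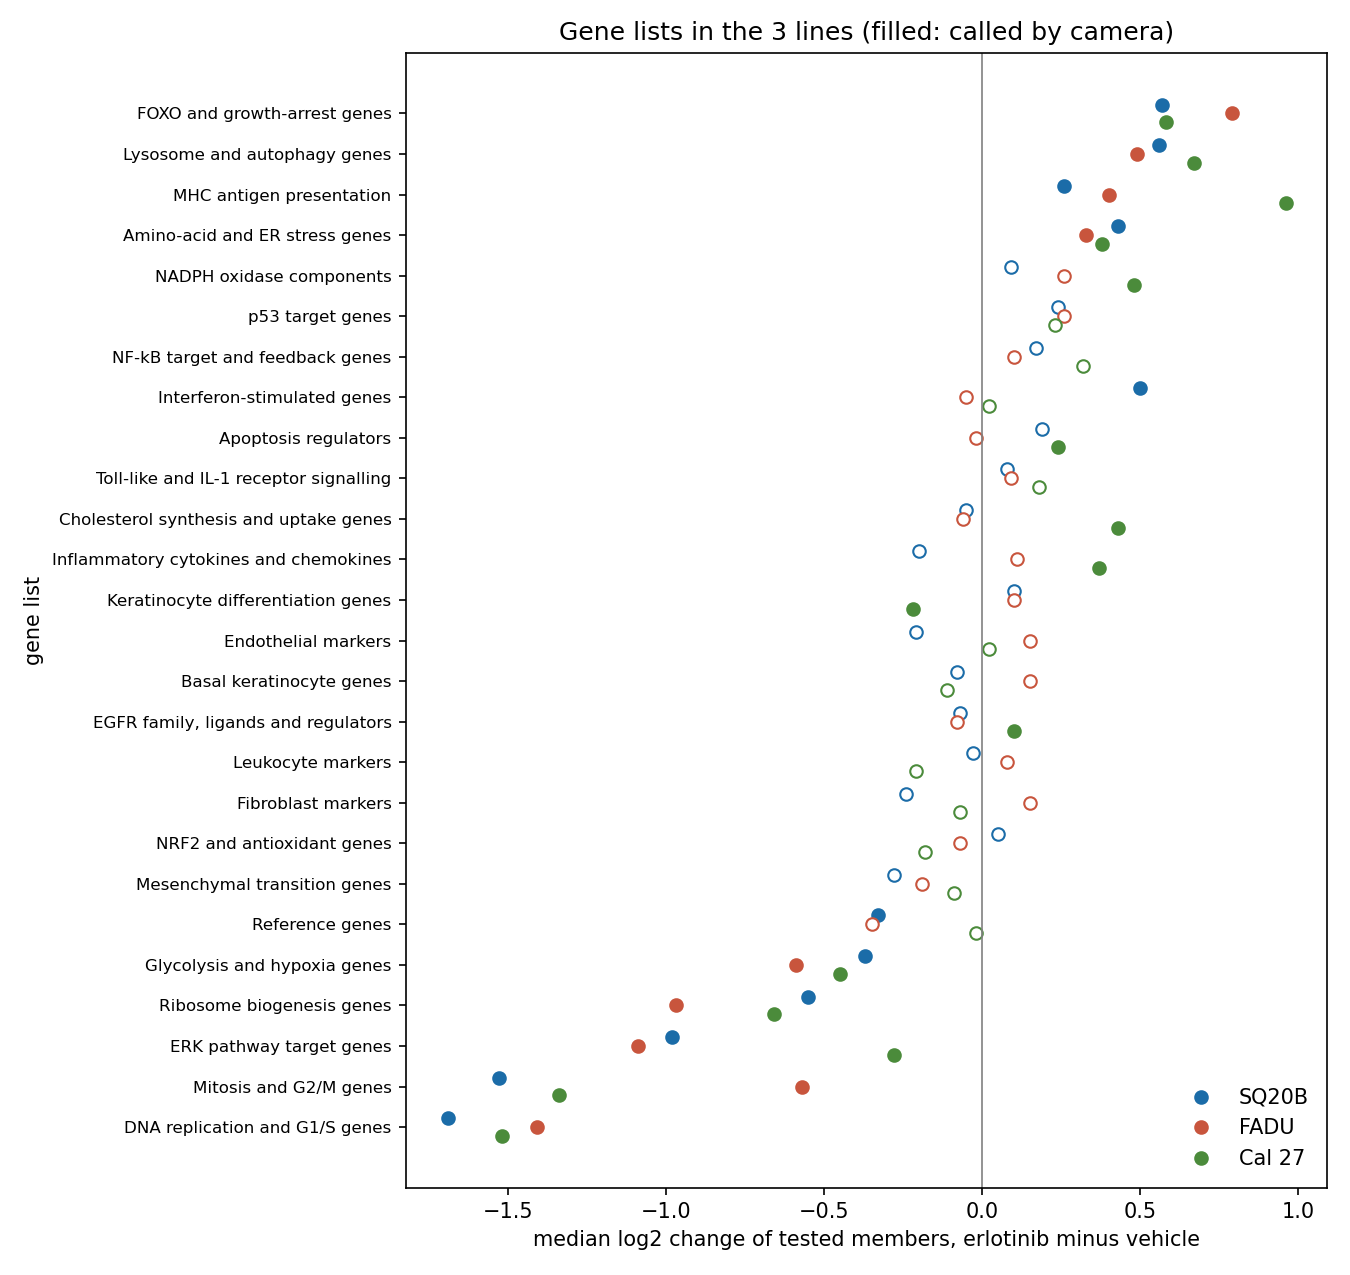
Median log2 change of the members of each gene list in SQ20B, FADU and Cal 27. Filled points were called by camera at an adjusted p below 0.05.

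The next question was which responses the lines shared. A total of 1452 genes were called in the same direction in all 3 lines, 641 risen against 47.4 expected from independent lists and 811 fallen against 44.7. Among the shared rises were CYP1A1 and CYP1B1, enzymes induced by aryl hydrocarbon receptor ligands, with CYP1B1 at 1.91, 2.85 and 2.03 in SQ20B, FADU and Cal 27. LCN2 rose by 1.99, 3.31 and 2.01, KLHL24 by 1.92, 2.01 and 2.06, the iron reductase gene CYBRD1 by 1.90, 2.30 and 1.92, and the histone gene H2BC5 by 1.87, 2.48 and 2.66. VTCN1, a B7 family gene, rose by 1.75 in SQ20B, 1.82 in Cal 27 and at least 3.28-fold in FADU, where no vehicle array detected it. MXD4, a MYC antagonist, rose by 1.74, 2.23 and 1.76, YPEL5 by 1.66, 1.86 and 1.81, and RARRES1 by 1.77, 1.76 and 1.79. The shared falls included genes of DNA replication, with MCM10 at -2.18, -1.81 and -2.13, GINS2 at -2.12, -1.75 and -2.14, POLE2 at -1.98, -1.70 and -2.06, and MCM2 at -1.70, -1.82 and -1.74. TRIP13, a mitotic checkpoint gene, changed by -2.22, -2.06 and -1.96, and LRP8 by -2.21, -2.83 and -1.82. The highest limma adjusted p with Benjamini-Hochberg among these 20 genes in any line was 1.5e-06, for EGR1. Across genes, which are not independent replicates, log2 changes correlated at 0.6 between SQ20B and FADU, 0.58 between SQ20B and Cal 27, and 0.6 between FADU and Cal 27. Calls in opposite directions numbered 79, 104 and 127 for SQ20B with FADU, SQ20B with Cal 27, and FADU with Cal 27, against 580.2, 539 and 737 expected. In at least 1 line 7172 genes were called.

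The last question was where the response differed between lines, tested as the difference of the erlotinib effects in limma with Benjamini-Hochberg adjustment. Between SQ20B and FADU 1340 genes differed, 597 with the higher change in SQ20B. TAGLN rose in SQ20B and was not called in FADU (0.24), a difference of 2.96 (SE 0.31, limma adjusted p = 1.01e-05). KRT16 differed by 2.40 (SE 0.32), the chemokine gene CCL5 by 2.07 (SE 0.28), and ISG20, which rose in SQ20B (0.85) and fell in FADU, by 2.12 (SE 0.23). NUPR1 had a log2 change of 0.23 in SQ20B, not called, and differed by -3.57 (SE 0.27, adjusted p = 3.78e-07). HES2, a transcriptional repressor gene, rose by 2.92 (SE 0.17) in FADU and differed by -3.08 (SE 0.24), and S100P and VGLL1 each differed by -2.58. IL6 rose more in SQ20B, by 1.14 (SE 0.21, adjusted p = 0.00215). DUSP6 had a larger log2 fall in SQ20B, with a difference of -1.57 (SE 0.28, adjusted p = 0.00137). Its mean went from 8.93 to 5.76 in SQ20B and from 7.23 to 5.63 in FADU. Both erlotinib means lay near the detection limit, so the difference follows the vehicle levels. It does not rank the lines by how far DUSP6 was suppressed. EGFR differed by -0.94 (SE 0.22, adjusted p = 0.0109). Other EGFR probes changed by 0.20, -0.16 and -0.20 in SQ20B, none called. In the same order they changed by 0.87 (called), -0.26 and 0.09 (both not called) in FADU. The mitosis and G2/M list fell further in SQ20B, with a median difference of -0.92 (camera adjusted p = 5.47e-22), and the ribosome biogenesis list fell further in FADU, with a median difference of 0.39 (camera adjusted p = 1.74e-05). Interferon-stimulated genes differed by a median of 0.81 (camera adjusted p = 3.48e-08, but adjusted p = 0.387 with an estimated correlation).

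Between Cal 27 and FADU 1417 genes differed, 717 with the higher change in Cal 27. KRT13 fell in Cal 27 and rose in FADU, a difference of -5.02 (SE 0.26, limma with Benjamini-Hochberg, adjusted p = 2.55e-09). KRT4 differed by -3.03 (SE 0.24), with detection on 2 of 3 Cal 27 erlotinib arrays, and FGD3, which rose by 2.94 (SE 0.21) in FADU, differed by -3.33 (SE 0.30). The histone genes H2BC4 and H2BC6 rose in Cal 27 (both 1.31) and fell in FADU (-1.72 and -1.66), with differences of 3.04 (SE 0.21) and 2.97 (SE 0.28). CXCL8 rose in Cal 27 and fell in FADU, a difference of 2.53 (SE 0.21, adjusted p = 8.04e-07), and IL1B and IL1A differed by 1.26 (SE 0.24, adjusted p = 0.00218) and 1.21 (SE 0.29, adjusted p = 0.00998). ERK pathway target genes differed by a median of 0.61 (camera adjusted p = 1.1e-06), cytokines by 0.50 and MHC antigen presentation genes by 0.37 (both camera adjusted p = 4.39e-05), cholesterol genes by 0.62 (camera adjusted p = 2.28e-05) and mitosis genes by -0.78 (camera adjusted p = 1.86e-15). Cal 27 arrays had been normalized apart from the other lines, so line and array set cannot be told apart in this difference or the next.

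Between Cal 27 and SQ20B 1044 genes differed, 585 with the higher change in Cal 27. KRT13, which rose by 0.61 (SE 0.19) in SQ20B, differed by -3.58 (SE 0.26, limma with Benjamini-Hochberg, adjusted p = 2.71e-07), and KRT16 by -2.30 (SE 0.32, adjusted p = 0.00014). NUPR1 differed by 2.82 (SE 0.27), SHISA2, which changed by -2.44 (SE 0.22) in SQ20B, by 2.90 (SE 0.31), and ABCA13, detected on no SQ20B array and no Cal 27 vehicle array, by 3.32 (SE 0.34), a value that depends on the offset. CXCL8 differed by 1.97 (SE 0.21, adjusted p = 1.3e-05), DUSP6 by 1.49 (SE 0.28, adjusted p = 0.00214) and MYC by 0.98 (SE 0.19, adjusted p = 0.00258). The MYC difference rests on 1 probe, as its other probe fell in both lines (-0.53 in SQ20B and -0.43 in Cal 27). ERK pathway target genes fell less in Cal 27, with a median difference of 1.00 (camera adjusted p = 1.76e-09). MHC antigen presentation genes differed by a median of 0.47 (camera adjusted p = 1.41e-05) and cholesterol genes by 0.45 (camera adjusted p = 4.95e-05). The offset in the deposited log2 values holds down changes of dim genes. With no offset and intensities under 1 set to 1, log2 changes in FADU were -2.68 for DUSP6, -2.88 for IRS1, 2.61 for WIPI1, 2.74 for RARRES1 and -1.96 for AKR1B10. They were -2.12 for MMP1 in SQ20B and -2.63 for AKR1B10 in Cal 27. Where a group did not detect a gene, as for ABCA13, ETV5 and VTCN1, such values are set by the floor of 1 and are not given.

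**Figure D3:**
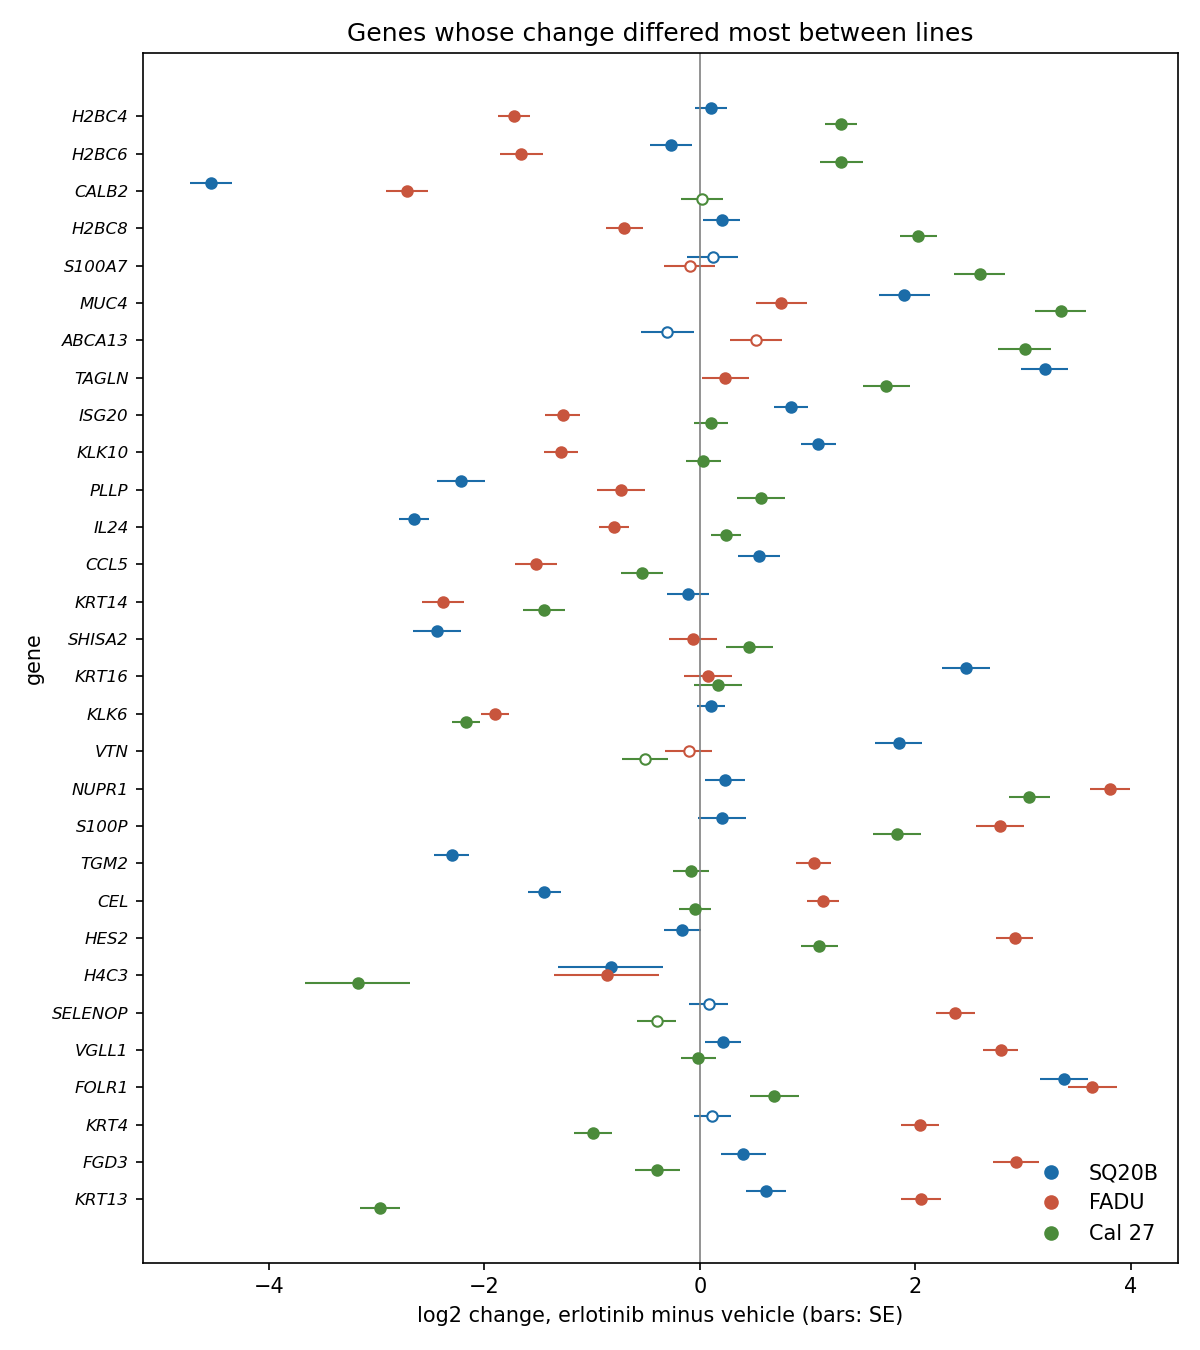
Log2 change with erlotinib, with SE, in each line for 30 genes that differed between lines. Open points mark lines in which no array detected the gene.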

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

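The results below were singled out because the erlotinib effect differed between 2 lines at a limma adjusted p below 0.05 with Benjamini-Hochberg adjustment, and none of the tests in this part was chosen after the values were seen except camera on list differences and the fits without 2 Cal 27 arrays. Between SQ20B and FADU, TAGLN differed by 2.96, KRT16 by 2.40, KLK10 by 2.39, KRT14 by 2.28, ISG20 by 2.12 and CCL5 by 2.07. With no offset KRT14 was not called (2.35, adjusted p = 0.247), and its probe was detected on 1 SQ20B vehicle array and 0 erlotinib arrays. The 1 other probe of KLK10 was not called in SQ20B (0.30) or FADU (-0.29). VGLL1 and S100P differed by -2.58 each, CEL, a lipase gene, by -2.59, HES2 by -3.08, TGM2, a transglutaminase gene, by -3.36 and NUPR1 by -3.57. TGM2 rose in FADU by its named probe, with 0.04 and 0.10 at 2 others. Among the genes named whatever their result, DUSP6 differed by -1.57 (levels given above), EGFR by -0.94 (other probes given above) and IL6 by 1.14. List medians differed by 0.81 for interferon-stimulated genes (adjusted p = 0.387 with an estimated correlation), 0.33 for NRF2 and antioxidant genes (camera adjusted p = 0.0308, but adjusted p = 0.778 with an estimated correlation), -0.30 for DNA replication and G1/S genes (camera adjusted p = 0.00595, but adjusted p = 0.387 with an estimated correlation), -0.92 for mitosis and G2/M genes and 0.39 for ribosome biogenesis genes.

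Between Cal 27 and FADU, H2BC4 differed by 3.04, H2BC6 by 2.97, H2BC8 by 2.73, CALB2 by 2.73, S100A7 by 2.69 and MUC4 by 2.59. CALB2 was detected on no Cal 27 array, and its FADU probes were called in opposite directions (-2.71 and 0.79). S100A7, an antimicrobial peptide gene, was detected on no FADU array and was not called with no offset (3.10, adjusted p = 0.23). The 2 other probes of MUC4 were not called in any line. SELENOP, a selenium transport gene detected on no Cal 27 array, differed by -2.77, VGLL1 by -2.81, FOLR1 by -2.95, KRT4 by -3.03, FGD3 by -3.33 and KRT13 by -5.02. FOLR1, detected in Cal 27 on 0 vehicle and 2 erlotinib arrays, was not called with no offset (-2.43, adjusted p = 0.206). CXCL8 differed by 2.53, IL1A by 1.21, IL1B by 1.26 and IL6 by 0.77, where the IL6 call was lost without FADU vehicle array 3, FADU erlotinib array 2 or Cal 27 vehicle array 3 (0.75, 0.65 and 0.65, limma adjusted p = 0.0564, 0.0686 and 0.0679). It was also lost with neqc (0.67, adjusted p = 0.0655), no offset (0.53, adjusted p = 0.259) and no detection filter (adjusted p = 0.0515). List medians differed by 0.61 for ERK pathway target genes, 0.50 for cytokines, 0.37 for MHC antigen presentation genes, -0.78 for mitosis genes and 0.62 for cholesterol genes. They differed by 0.13 for EGFR family genes, -0.20 for DNA replication genes, 0.29 for ribosome biogenesis genes, 0.38 for glycolysis and hypoxia genes and -0.39 for keratinocyte differentiation genes (camera adjusted p = 0.0306, 0.0129, 0.00299, 0.0283 and 0.000151). The last 5 were not called at adjusted p = 0.27, 0.27, 0.0914, 0.266 and 0.134 with an estimated correlation.

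Between Cal 27 and SQ20B, CALB2 differed by 4.55, with 1 of its 2 probes not called in SQ20B (0.28), ABCA13 by 3.32, SHISA2 by 2.90, IL24 by 2.90, NUPR1 by 2.82 and PLLP by 2.79. IL24 was detected on 0 vehicle arrays and 1 erlotinib array of Cal 27. KLK6, a protease gene, differed by -2.27, KRT16 by -2.30, H4C3 by -2.35, VTN by -2.35, FOLR1 by -2.69 and KRT13 by -3.58. H4C3 lost its call in 10 of 12 fits without 1 array (-2.51 to -1.77, limma adjusted p = 0.0591 to 0.114), all except those without Cal 27 vehicle array 2 or erlotinib array 2. It was also lost with no offset, no detection filter, an intensity trend, and without both Cal 27 vehicle array 2 and erlotinib array 3 (adjusted p = 0.105, 0.0691, 0.105 and 0.0504). FOLR1, with the same Cal 27 detection as above, was not called with no offset (-1.0, adjusted p = 0.665). In that setting PLLP was at 4.27, while VTN, IL24, SELENOP and ABCA13 had larger differences set by the floor of 1 in undetected groups. VTN, the vitronectin gene, rose at least 2.03-fold in SQ20B and was detected on no Cal 27 array, and the other KLK6 probe was not called in Cal 27 (-0.17). CXCL8 differed by 1.97, DUSP6 by 1.49, MYC by 0.98 and MYD88 by -0.76. The other MYC probe fell in both lines (-0.53 and -0.43), so its difference rests on 1 probe. The MYD88 call was lost in 9 of 12 fits (-0.81 to -0.65, limma adjusted p = 0.0573 to 0.103), and kept without SQ20B vehicle array 3, Cal 27 vehicle array 1 or Cal 27 erlotinib array 1. It was also lost with no offset (-0.89, adjusted p = 0.0731), no detection filter (adjusted p = 0.0804) and without the same 2 Cal 27 arrays (-0.72, adjusted p = 0.0967). List medians differed by 1.00 for ERK pathway target genes, 0.47 for MHC antigen presentation genes and 0.45 for cholesterol genes. They differed by 0.50 for EGFR family genes, 0.41 for cytokines, -0.67 for interferon-stimulated genes, -0.38 for NRF2 and antioxidant genes and -0.26 for keratinocyte differentiation genes (camera adjusted p = 0.000234, 0.000416, 7.41e-07, 0.00538 and 1.41e-05). These 5 were not called at adjusted p = 0.0793, 0.0766, 0.227, 0.323 and 0.0793 with an estimated correlation.

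Array labels were reassigned to see how many calls arise from other groupings. Within a line there are 10 splits into 3 and 3 arrays, too few for a share under 0.05. The real split gave 4279 genes in SQ20B, 4599 in FADU and 2744 in Cal 27, and the highest other split gave 0, 0 and 44, so that 1 of 10 reached the real count each time. These fits used the 6 arrays of a line with the deposited values and the genes and probes of the full model, whereas the alternative of each line alone also normalized and filtered within the line. For gene lists the real splits gave 11, 9 and 17, and the highest others 10, 9 and 7, reached by 1, 2 and 1 of 10. Each other split holds 2 of 3 arrays of a treatment on a side and so carries part of the treatment effect. For differences between lines, the 12 arrays of each pair of lines were centred by line and fitted alone, so counts differ from those of the full model. Here 1 of 100 reassignments reached the real counts, which were 1782, 940 and 891 for SQ20B minus FADU, Cal 27 minus FADU and Cal 27 minus SQ20B, with 0, 1 and 0 as the highest others. For genes shared by all lines 1 of 100 reached 1452, the highest other being 1. The real grouping is among those counted in each case. Reassigned groups mix arrays of different treatments or lines, which widens the spread of every gene whose response differs between them. Their low counts therefore do not measure how many calls arise without an effect.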

How the results depend on the processing

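The replicate block (pairing arrays by number within a line) gave 2858, 4124 and 3716 called genes in SQ20B, FADU and Cal 27, 1224 shared by all lines, and 827, 902 and 622 differences between SQ20B and FADU, Cal 27 and FADU, and Cal 27 and SQ20B, against 1340, 1417 and 1044 without it. Deviations of arrays with the same number correlated across genes at -0.44 to 0.05, and those of a Cal 27 pair with unequal numbers at 0.34. These values gave no sign that equal numbers mark paired samples. Deviations from means of 3 arrays cannot settle this, and the labels do not say. With all 18 arrays quantile-normalized together, values under 1 set to 1 and no offset, the last difference held 650 genes. The planned neqc gave 3581, 4880 and 4167 genes and 1466 shared. Each line alone gave 4551, 4861 and 3103, and 1410 shared. Leaving out 1 array gave 2668 to 2800 genes in SQ20B, 3831 to 4400 in FADU and 3563 to 4141 in Cal 27, 924 to 1441, 1059 to 1515 and 738 to 1102 differences in the order above, 1232 to 1422 shared genes, and 11 to 12, 9 to 9 and 13 to 15 lists. Without Cal 27 vehicle array 2 and erlotinib array 3, chosen after the data were seen because their deviations correlated at 0.34, Cal 27 had 3799 genes, 14 lists, and 1245 and 1098 differences from FADU and SQ20B, with 1362 shared genes. The call counts of 11, 9 and 15 lists became 9, 7 and 8 with an estimated correlation. With fry, which tests a list against no change rather than against the other genes, they were 19, 18 and 24. CALB2 turned direction without an offset, at 0.55 in SQ20B, 1.16 in FADU, -0.98 for Cal 27 minus FADU and -0.37 for Cal 27 minus SQ20B, where its other probe had the higher mean and was used. The remaining turns concerned values that were not called, and their cause was not tested. DUSP6 for Cal 27 minus FADU was 0.44 without an offset, 0.0949 with neqc, and -0.29 to 0.07 without 1 array. Without the 2 Cal 27 arrays CCND1 for Cal 27 minus FADU was -0.0563 and MYD88 in Cal 27 was 0.0159. Without 1 array CCND1 ranged from -0.0803 to 0.279 for Cal 27 minus FADU and from -0.21 to 0.15 for Cal 27 minus SQ20B, EGFR in SQ20B from -0.0651 to 0.0984, and MYC in Cal 27 from -0.0534 to 0.179. MYD88 ranged from -0.124 to 0.0859 in Cal 27, from -0.0896 to 0.231 in FADU, and from -0.251 to 0.069 for Cal 27 minus FADU. IL6 in FADU was called with neqc (0.466, limma adjusted p = 0.0298), no offset (0.624, adjusted p = 0.0173), the stricter filter (adjusted p = 0.0497), the intensity trend (adjusted p = 0.0474) and without FADU erlotinib array 2 (0.493, adjusted p = 0.0254). For SQ20B minus FADU, IL1A (0.83, limma adjusted p = 0.0265) and IL1B (0.79, adjusted p = 0.0343) were called without FADU erlotinib array 3. MYD88 was called there without FADU erlotinib array 2 (0.83, adjusted p = 0.019). The block ended 22 calls among 385 results on named genes, among them IL1B in SQ20B, IL6 for Cal 27 minus FADU, and MYD88 and H4C3 for Cal 27 minus SQ20B (adjusted p = 0.0745, 0.0593, 0.0686 and 0.108). A slide block was not run, since the columns name no slide, and the authors' processed values, listed as an alternative, were the values used.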

Other observations

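Histone genes were not among the fixed lists, and 51 of them were tested. In SQ20B 13 rose and 4 fell, in FADU 14 rose and 17 fell, and in Cal 27 25 rose and 6 fell. Of these genes 10 rose in all 3 lines and 0 fell in all 3. H2BC21 rose by 1.5 (SE 0.14), 2.00 (SE 0.14) and 2.97 (SE 0.14) in SQ20B, FADU and Cal 27, H2AC6 by 1.88, 1.48 and 2.70 (SE 0.17 each), and H4C14 by 1.62, 1.55 and 1.60 (SE 0.15 each). In FADU H3C3 changed by -2.32 (SE 0.24), H2BC9 by -2.09 (SE 0.20) and H3C12 by -1.89 (SE 0.22). H2BC4, H2BC6, H2BC7, H2BC8 and H3C7 fell in FADU and rose in Cal 27. Many genes within a histone family, such as H2B, are near-identical copies, so a probe can carry signal of other members of its family.

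Target genes of the aryl hydrocarbon receptor formed another group, of which NQO1, SLC7A5, IL1B and EREG belonged to fixed lists as well. Beside CYP1A1 and CYP1B1, 12 genes of a receptor list were tested, of which 6 rose and 1 fell in SQ20B, 8 rose and 2 fell in FADU, and 6 rose and 0 fell in Cal 27. The fallen genes were IL1B in SQ20B, a call lost without 1 of several arrays, and IL1B and EREG in FADU. ALDH3A1, an aldehyde dehydrogenase gene, rose by 1.33, 2.37 and 1.64 (SE 0.12 each), UGT1A6, a glucuronosyltransferase gene, by 1.35, 2.16 and 2.28 (SE 0.15 each), NEDD9 by 1.16, 1.85 and 1.13 (SE 0.16 each) and TIPARP by 0.71, 1.06 and 0.90 (SE 0.14 each). NQO1, also a target of NRF2, was not called in any line (0.31, 0.22 and -0.18, SE 0.13 each).

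Of the tests in this part, the neqc tests of CYP1A1, CYP1B1 and CXCL8, the tests of signal shared by histone probes with their interval rule, and the median over all 12 receptor genes were chosen after the values were seen, and the others were written before them.

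The rise of CYP1A1 and CYP1B1 in all 3 lines may reflect activation of the aryl hydrocarbon receptor under erlotinib, which is a hypothesis of this text. The test set in advance left out IL1B and EREG, and its 10 genes had median log2 changes of 0.55, 0.73 and 0.65, the lowest 0.554, above a bound of 0.3, against 0.36, 0.50 and 0.32 over all 12. Separate normalization of the 2 array sets does not account for the rise, since each contrast lies within 1 set. With all 18 arrays normalized together by neqc both genes were called in every line with a log2 change of at least 2.00. That check started from values already normalized within each set. Other technical explanations, and whether the receptor is needed, were not tested. Erlotinib treatment of these lines after AHR knockout or with a receptor antagonist would test it, with CYP1A1, ALDH3A1 and UGT1A6 as readouts.

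Histone genes moving in both directions could come from a single signal shared by all histone probes. Called genes of a line would then move 1 way. In FADU 14 called genes rose and 17 fell, each by its own test (45.2% against the majority). So 1 signal across all of them is not the whole cause there, though several signals stay open. In SQ20B (23.5%) and Cal 27 (19.4%), where 4 and 6 genes went against the majority, 1 signal stays open as well. These counts pool the H1, H2A, H2B, H3 and H4 families, so they do not test signal shared among copies within a family. In FADU all called H3 genes fell and all called H4 genes rose. Called H2B genes went both ways there, such as H2BC21 (2.00, SE 0.14) and H2BC9 (-2.09, SE 0.20). Signs were equal in 42 of 47 pairs of calls in 2 lines (89.4%), a count in which 10 genes called in all 3 lines enter several times, and which leaves open whether histone genes as a group move alike. All 5 unequal pairs were among the 21 of FADU with Cal 27. H2BC4, H2BC6, H2BC7, H2BC8 and H3C7 differed there by 3.04, 2.97, 1.82, 2.73 and 1.89 (highest limma adjusted p = 0.000105). These 5 were picked by their opposite calls in the same values, so their difference tests add no separate support. Most are H2B genes, whose probes may share signal, and line and array set cannot be told apart in this difference. Sequencing of polyadenylated and total RNA from the same cultures might separate copies and transcript ends.

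CXCL8 fell in SQ20B and FADU and rose in Cal 27, and its second probe changed the same way (-1.03, -1.24 and 1.13, all called). Each change lies within 1 array set, so separate normalization alone does not account for the opposite directions. They could be a property of Cal 27 or of another feature of its set of arrays. Within arrays the CXCL8 percentile rose from 98.5 to 99.2 in Cal 27, with the lowest erlotinib array 0.4 points above the highest vehicle array. That restates the rise, since ranks follow values in arrays normalized together. The call did not rest on 1 array, the highest limma adjusted p without any array being 0.00212. With all 18 arrays normalized together by neqc the differences from FADU and SQ20B were 2.74 and 2.09. These intensities had already been normalized within each set, so the directions could hardly change. The check shows only that the differences remained on a common scale. Line and array set cannot be told apart. A quantitative PCR or secreted protein assay of CXCL8 in all 3 lines on shared plates would test it.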
